A study of Mus musculus with 2 samples.

How the data were processed

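RNA was profiled in primary mouse hepatic stellate cells, the pericytes of the liver sinusoid that become matrix-producing myofibroblasts in injury and in culture on plastic. The cells carried floxed alleles of Adar, which encodes the double-stranded RNA adenosine deaminase ADAR1, and the tamoxifen-activated recombinase Cre-ER. They were given vehicle or 100 nM 4-hydroxytamoxifen (4-OHT) and cultured for 4 days. There was 1 library per group, and the libraries were grouped by the treatment in their labels. No spread between replicates could be measured, so no test across replicates was made.

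The deposited table held 1 FPKM value (fragments per kilobase of transcript, scaled to the size of the library) per gene and library, per the file headers. STAR, Cufflinks and the mouse build GRCm38 were named in the submitters' processing notes without versions or roles. The scaling between libraries was not given in the sources used here. The deposited log2 fold change was the log2 of the 4-OHT FPKM plus 1 over the vehicle FPKM plus 1, which held within 1e-09 in all 17145 rows. The p-value and q-value columns were deposited by the authors, per the file headers. How that test estimated the spread without replicates was not given in the sources used here, and its p-values compare these libraries, not the conditions. All 17145 versioned gene identifiers matched GENCODE M21 on GRCm38, from which coordinates, gene types and transcript lengths were taken. In 20 rows the gene symbol had been turned into a date and was restored from the identifier. Of 17128 symbols, 17 stood on more than 1 row, and the row with the largest sum was used.

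Depth was recovered from the low values. Among genes with 1 annotated transcript longer than 600 bases, FPKM multiplied by an effective length fell on whole steps, of 0.0259 FPKM times kilobases in the vehicle library and 0.0328 in the 4-OHT library. The effective length was the transcript length less 177 bases and 170 bases. With these steps, 97.5% of 1186 low values in the vehicle library and 98.3% of 1217 in the 4-OHT library were within 0.1 of a whole number of fragments, against 20% by chance. Thus 1 FPKM over 1 kilobase of effective length stood for 38.6 fragments with vehicle and 30.5 with 4-OHT, a relative depth of 0.790. For single-transcript genes, fragments gave a ratio of FPKM with an exact 95% interval. A gene listed at 0 was set to a floor of 3 fragments in its library. The fold was then a lower bound for the value listed in the other library, whose own counting error it leaves out. PCR copies could not be told from molecules, so intervals and floors cover counting error only.

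Changes were computed as the log2 of FPKM plus a pseudocount of 1, 4-OHT over vehicle, which understates the change of low genes. Genes with at least 1 FPKM in the higher library were counted as higher or lower when the change reached 2-fold. For each of 35 gene lists fixed beforehand, the median change of the measured members was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. Lists with fewer than 3 measured members gave no percentile. A list was called when its median lay outside percentiles 2.5 to 97.5, which describes these libraries and is not a test across replicates. The lists covered ADAR enzymes, type I interferon-stimulated genes, interferon-gamma responsive genes, double-stranded RNA sensing, DNA sensing, interferons with their receptors, feedback regulators of interferon, MHC class I, MHC class II, and chemokines with cytokines. They further covered contractile genes, collagens and matrix, matrix remodelling, TGF-beta, PDGF and YAP signalling, quiescent stellate cells, the cell cycle, p53, cell death, stress responses, senescence, estrogen response, sterol synthesis, mitochondrially encoded transcripts and immediate early genes. The remaining lists held markers of hepatocytes, cholangiocytes, endothelium, macrophages, lymphocytes, neutrophils, dendritic cells, mesothelium, portal fibroblasts, smooth muscle and red cells. The groups, lists, thresholds and most alternatives were fixed before the data were examined.

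Named genes were the 10 with the highest and the 10 with the lowest change among genes with at least 5 FPKM in the higher library, leaving out predicted models, microRNA, snoRNA and receptor segments. To these were added the 3 measured members of each list with the largest absolute change (5 for type I interferon-stimulated genes) and a fixed set of stellate, interferon and RNA-sensing genes. Some genes that this rule takes are not reported here. Other genes, named to complete a short count or as members within 2-fold, were chosen after their values were seen. Adar, the floxed gene, was to be given first. It was not analysed here, so the libraries' labels could not be checked against the target.

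The percentile method was tested on simulated data built from the 13558 genes of this comparison. It recovered 100% of 50 lists of 20 genes raised 2-fold and 100% of 50 lists lowered 2-fold, likewise at 4-fold, and it called 4% of 400 lists of unchanged genes. The simulated genes varied independently of each other. The 4% therefore does not give the rate of calls for lists whose members move together, as genes of 1 cell type or pathway can. All 20 genes of each changed list were changed. The recovery therefore does not carry over to shorter lists or to lists changed in part. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. The alternatives were pseudocounts of 0.1 and 5, centring on the median change, trimmed-mean scaling, no minimum value and a minimum of 5 FPKM, summed rows of one symbol, other fold thresholds, random lists in 10 bins or unmatched, list means, lists without their type I interferon members, and a stricter q-value.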

Results

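The data were 2 RNA-seq libraries of cultured primary hepatic stellate cells from mice with floxed Adar and Cre-ER, 1 given vehicle and 1 given 4-OHT, which activates the recombinase. The comparison addressed how loss of ADAR1, an enzyme that edits adenosine to inosine in double-stranded RNA, alters gene expression during activation in culture. With n = 1 per group, no difference below has a replicate check, and every difference is between these libraries. FPKM summed to 493531 in the vehicle library and 553634 in the 4-OHT library, with medians of 6.10 and 6.09 and with 12953 and 12890 genes at 1 FPKM or more. A value of 1 FPKM over 1 kilobase of effective length stood for 38.6 fragments with vehicle and 30.5 with 4-OHT. Adar, the floxed gene (chromosome 3, 89715022 to 89753446, plus strand, GRCm38), was not analysed here. Of the ADAR enzyme list, Adarb1, which encodes the related deaminase ADAR2, was the 1 measured member, at 10.2 FPKM with vehicle and 4.83 FPKM with 4-OHT (log2 change −0.95).

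Interferon-stimulated genes were far higher in the 4-OHT library, and genes of matrix, the cell cycle and sterol synthesis were lower as groups, with 5 of 22 contractile genes at least 2-fold lower. Of 13558 genes with at least 1 FPKM in the higher library, 783 were at least 2-fold higher with 4-OHT, 472 were at least 2-fold lower and 12303 lay within 2-fold. The median change over these genes was 0.03 in log2, with quartiles of −0.25 and 0.30. At 4-fold the counts were 293 higher and 77 lower. Among the 11667 protein-coding genes, 562 were higher and 374 lower at 2-fold, and 200 and 26 at 4-fold. The 356 genes whose longest transcript was under 300 bases, where FPKM is least certain, held 118 of the higher and 81 of the lower genes. The authors' deposited table called 424 genes at a q-value under 0.05, 295 higher and 129 lower. A pseudocount of 5 gave 456 higher and 163 lower genes, and a pseudocount of 0.1 gave 859 lower genes.

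**Figure D1:**
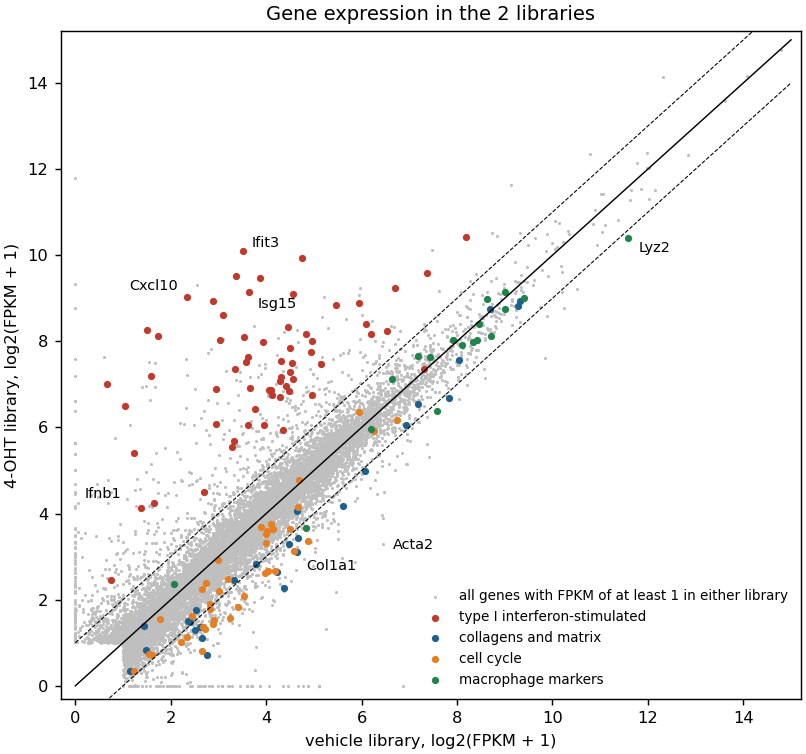
Each point is a gene, with log2(FPKM + 1) in the vehicle library on the horizontal axis and in the 4-OHT library on the vertical axis; the solid line marks equal values, the dashed lines 2-fold differences, and colours 4 of the gene lists. The type I interferon-stimulated genes (red) lie above the upper dashed line in 61 of 62 cases, and 26 of 27 collagen and matrix genes (blue) lie below the solid line.

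The 10 genes with the highest change were all genes known to respond to interferon. Ms4a4c, a membrane-spanning protein of leukocytes, was at 0.520 FPKM with vehicle and 196 FPKM with 4-OHT (log2 change 7.02). Mx1, an antiviral GTPase, was at 1.82 and 306 FPKM (6.76), and Cxcl10, a chemokine for T cells (chromosome 5, 92346638 to 92348889, minus strand), at 4.89 and 637 FPKM (6.76). Cmpk2, a nucleotide kinase next to Rsad2, was at 4.05 and 521 FPKM (6.69), and Rsad2, the antiviral enzyme viperin, at 9.25 and 735 FPKM (6.17). Ifit3, which binds viral RNA complexes (chromosome 19, 34583531 to 34588731, plus strand), was at 10.3 and 1093 FPKM, a ratio of 106 with a 95% counting interval of 97.7 to 115. Its neighbours Ifit3b (6.39), Ifit1bl1 (6.34) and Ifit1 (6.04) had changes of similar size. Ifi206, a member of the Ifi200 family of DNA-binding proteins, was at 1.91 and 183 FPKM (5.98). Ifit3 and Ifit3b are near-identical copies, so the split of fragments between them is uncertain, and the Ifi200 genes share sequence in part.

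Of 62 measured type I interferon-stimulated genes, 61 were at least 2-fold higher and none was at least 2-fold lower. Their median change of 2.95 lay above those of all 10000 matched random lists, which reached at most 0.29. The member within 2-fold was Ifi30, a lysosomal thiol reductase, at 158 and 163 FPKM. Isg15, a ubiquitin-like modifier (chromosome 4, 156199424 to 156200818, minus strand), was at 11.4 and 567 FPKM, a ratio of 49.7 (95% counting interval 43.9 to 56.5). Irf7, the transcription factor that amplifies interferon transcription, was at 25.9 and 979 FPKM (log2 change 5.19). Beside them, the median of macrophage markers was −0.21, that of immediate early genes 0.54 and that of 6 lymphocyte markers 0.64 (mean 0.31). The authors' deposited table called 54 of the 62 genes higher at a q-value under 0.05. Of 26 measured interferon-gamma responsive genes, mostly guanylate-binding proteins and immunity-related GTPases, 24 were higher, with a median of 3.33, above all random lists. Among them Gbp5 was at 1.63 and 121 FPKM (5.53), the chemokine gene Cxcl9 at 1.95 and 98.6 FPKM (5.08) and Gbp4 at 4.09 and 149 FPKM (4.88). The Gbp genes share sequence, and their split is uncertain. Type I interferon can induce many of the same genes, so this list does not tell the 2 kinds of interferon apart. Ifng, which encodes interferon gamma, was at 0.151 and 0.569 FPKM, below the minimum of 1.

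Interferon genes themselves were detected in the 4-OHT library. Ifnb1, which encodes interferon beta (chromosome 4, 88522025 to 88522774, minus strand), was listed at 0 with vehicle and at 21.6 FPKM with 4-OHT, equal to 382 fragments. Against the vehicle floor of 0.136 FPKM this was at least 159-fold higher. Ifna4, an interferon alpha gene, was listed at 0 and at 2.10 FPKM, equal to 25 fragments. This was at least 10.4-fold higher if the 25 fragments are taken without counting error. Jak2, a receptor-associated kinase, was at 32.2 and 77.5 FPKM (log2 change 1.24), while the receptor genes Ifnar1 (40.4 and 34.0 FPKM) and Ifngr1 (41.8 and 36.4 FPKM) lay within 2-fold. Of the 10 measured interferons and receptors, 3 were higher and 7 within 2-fold, and the list median of 0.35 lay at percentile 95.7, inside the range of random lists. With a pseudocount of 5, no minimum value, unmatched random lists or the list mean, this list lay outside that range.

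Sensors of double-stranded RNA were higher in part. Of 24 measured genes of this list, 14 were higher and 10 within 2-fold, with a median of 1.79, above all random lists. Zbp1, a sensor of left-handed nucleic acid that triggers necroptosis, was at 7.20 and 259 FPKM (log2 change 4.99). Ifih1, which encodes the sensor MDA5, was at 17.7 and 203 FPKM (3.45), Ddx58, which encodes RIG-I, at 35.2 and 198 FPKM (2.46), and Eif2ak2, which encodes the kinase PKR, at 24.3 and 86.3 FPKM (1.78). Oas3, a synthase of the RNase L activator, was at 11.2 and 198 FPKM (4.02). The relay genes Mavs (12.9 and 11.2 FPKM, −0.18) and Irf3 (38.1 and 36.1 FPKM, −0.07) lay within 2-fold. Without its members that were also on the type I list, the list's median was 0.79 over 17 genes, still above all random lists. These 17 still held Ifih1, Ddx58 and Eif2ak2, which interferon can also induce. The median therefore does not set RNA sensing apart from the interferon response. Of 10 DNA sensing genes, 6 were higher, with a median of 1.88, and 0.70 over the 7 genes outside the type I list. Trex1, a DNA exonuclease that stayed among the 7, was at 11.7 and 143 FPKM (3.50) and Ifi204 at 43.1 and 455 FPKM (3.37). The same limit holds for these 7 genes. Of 17 feedback regulators, 8 were higher, with a median of 0.91, among them Usp18, which blocks the interferon receptor, at 7.58 and 391 FPKM (5.51) and Dhx58 at 6.88 and 93.6 FPKM (3.59).

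Antigen presentation and inflammatory genes were also higher. Of 24 MHC class I genes, 21 were higher and none lower by 2-fold, with a median of 2.07, above all random lists. H2-Q6 was at 6.19 and 227 FPKM (log2 change 4.98), H2-Q7 at 4.67 and 119 FPKM (4.40) and H2-Q4 at 23.9 and 304 FPKM (3.62), with fragments divided uncertainly among these near-identical genes. Of 8 MHC class II genes, 1 was higher, Cd74, the invariant chain, at 64.4 and 198 FPKM (1.60); H2-Aa (0.87) and the protease gene Ctss (0.77) lay within 2-fold, and the median of 0.68 lay at percentile 99.8, or 96.6 for the list mean. Of 40 chemokines, cytokines and NF-kB targets, 26 were higher, with a median of 1.49, above all random lists. Immediate early genes and 6 lymphocyte markers had medians of 0.54 and 0.64. Ccl5, a chemokine for T cells and monocytes, was at 2.16 and 181 FPKM (5.84).

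**Figure D2:**
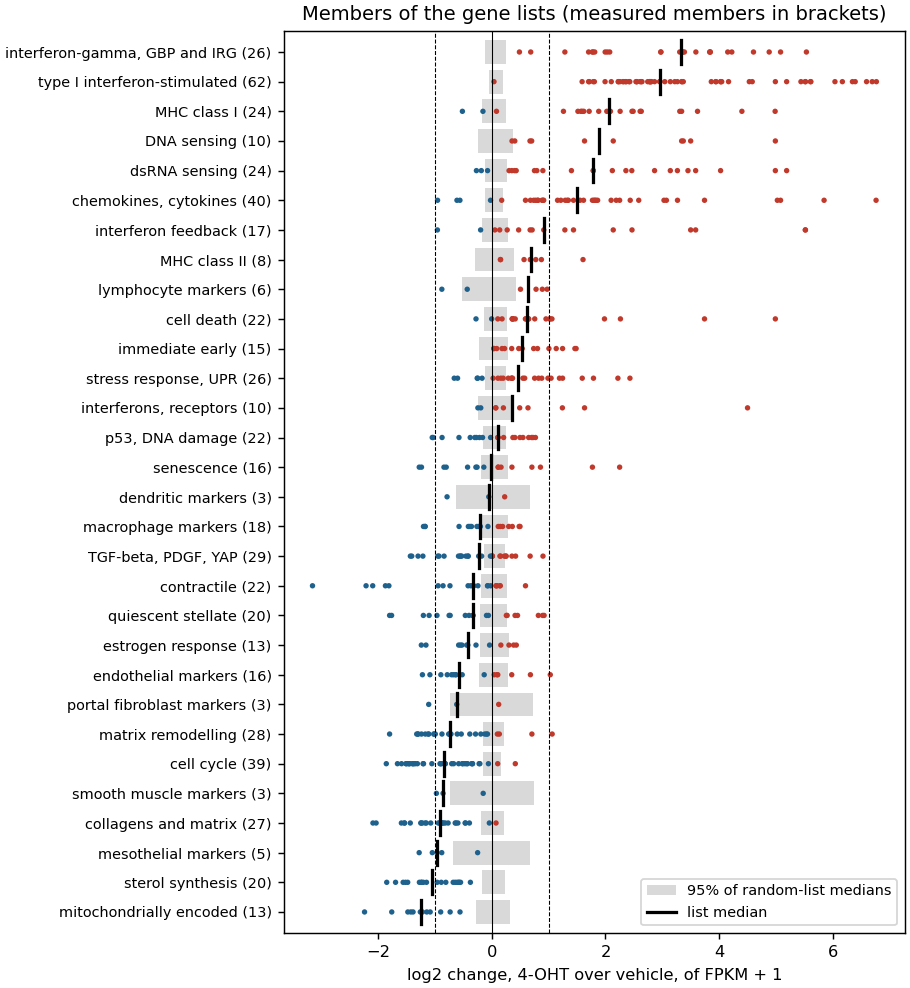
Each point is a measured gene of a list fixed beforehand, at its log2 change of FPKM + 1, 4-OHT over vehicle (red at or above 0, blue below); black bars mark list medians, grey bands the central 95% of medians of 10000 matched random lists, and dashed lines 2-fold. The medians run from 3.33 for interferon-gamma responsive genes to −1.24 for mitochondrially encoded transcripts.

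Collagen and matrix genes, and a part of the contractile genes, were lower in the 4-OHT library. Acta2, which encodes alpha smooth muscle actin, the usual marker of activation (chromosome 19, 34241090 to 34255590, minus strand), was at 86.8 FPKM with vehicle and 8.87 FPKM with 4-OHT (log2 change −3.15). Col1a1, a chain of collagen I (chromosome 11, 94936224 to 94953042, plus strand), was at 24.1 and 7.66 FPKM (−1.53), Col1a2, its partner chain, at 21.1 and 8.84 FPKM (−1.17) and Col3a1, collagen III, at 19.6 and 3.83 FPKM (−2.09). Of 27 measured collagens and matrix genes, 12 were at least 2-fold lower, none was higher, and 26 lay below 0. The list median of −0.92 lay below those of all 10000 random lists. Col12a1, a collagen of tendon and scar, was at 5.75 and 0.647 FPKM (−2.03) and Fbln2, an elastic-fibre protein, at 17.8 and 5.23 FPKM (−1.59). The basement membrane genes Col4a1 (638 and 485 FPKM) and Col4a2 (261 and 188 FPKM) lay within 2-fold. Beside these genes, the medians of macrophage and endothelial markers were −0.21 and −0.57, and that of mitochondrially encoded transcripts was −1.24. The medians of 5 mesothelial and 3 smooth muscle markers, cells that can also make matrix or contract, were −0.96 and −0.86. The mesothelial markers had a median of 1.27 FPKM with vehicle, where the added 1 shrinks the change. Without it, the ratio was 0.0823 for Upk3b, 0.0798 for Lrrn4 and 0.137 for Wt1, beside 0.318 for Col1a1 and 0.113 for Col12a1. Krt18, another mesothelial marker, differed less (1.23 and 0.880 FPKM). In the authors' deposited table, 7 of the 27 genes were called lower at a q-value under 0.05, with Col1a1 at 0.00466 and Col1a2 at 0.0527.

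Of 22 contractile genes, 5 were lower and 17 within 2-fold, and the median of −0.32 lay at percentile 0.08. Beside Acta2 the lowest were Myl9, a myosin light chain, at 30.8 and 5.86 FPKM (log2 change −2.21) and S100a6, a calcium-binding protein, at 169 and 38.8 FPKM (−2.09), followed by Tpm2 (−1.87) and Tagln (−1.81). Des, the intermediate filament desmin, was at 12.6 and 7.15 FPKM (−0.74), and Vim (630 and 666 FPKM) and Myh9 (253 and 281 FPKM), which many cell types express, lay within 2-fold. Of 28 matrix remodelling genes, 10 were lower and 1 higher, with a median of −0.74, below all random lists. Mmp9 was at 12.4 and 2.85 FPKM (−1.80), Mmp10 at 128 and 50.6 FPKM (−1.32) and the crosslinking enzyme gene Loxl1 at 1.82 and 0.147 FPKM (−1.30). Timp1, a protease inhibitor of fibrotic liver, was at 23.6 and 12.4 FPKM (−0.88), and the higher member was Timp3, at 61.3 and 129 FPKM (1.06).

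Of 29 genes of TGF-beta, PDGF and YAP signalling, 4 were lower and 25 within 2-fold, with a median of −0.23 at percentile 0.09, or −0.13 at percentile 3.11 for genes of at least 5 FPKM. Spp1, which encodes osteopontin, was at 94.8 and 34.5 FPKM (log2 change −1.43), with Tgfbi at −1.41 and Tgfb3 at −1.30. Pdgfrb, the PDGF receptor of stellate cells, was at 6.24 and 2.13 FPKM (−1.21), and Tgfb1, the main fibrogenic cytokine, at 52.5 and 58.6 FPKM (0.15). Genes of the quiescent stellate cell were not higher: of 20 measured, 4 were lower, none was at least 2-fold higher, and the median of −0.33 lay at percentile 0.23. Of these 20 genes 7 lay above 0, and the median was −0.14 at percentile 6.09 without a minimum value and −0.076 at percentile 17.2 for genes of at least 5 FPKM. Lrat, the retinol-storing enzyme, was at 1.36 and 0.209 FPKM (−0.96), a ratio of 0.154 (95% counting interval 0.104 to 0.222). Reln, reelin (−1.76), Rgs5, a pericyte gene (−1.20), and Fcna (−1.10) were lower. A pseudocount of 5 brought Col12a1 (−0.93), Col1a2 (−0.92) and Pdgfrb (−0.66), among other named genes, within 2-fold.

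The 10 lowest genes included Acta2. The lowest was S100a4, a calcium-binding protein of motile and mesenchymal cells (chromosome 3, 90603771 to 90606045, plus strand), at 37.1 and 1.501 FPKM (log2 change −3.93). Mgp, a matrix inhibitor of calcification, was at 12.6 and 0.294 FPKM (−3.39), and Scd2, a fatty acid desaturase, at 43.3 and 3.55 FPKM (−3.28). Sprr1a, a cornified envelope protein, was at 57.0 and 6.29 FPKM (−2.99), and Serpinf1, an anti-angiogenic serpin, at 12.7 and 0.855 FPKM (−2.89). Aqp1, a water channel, was at 47.3 and 6.84 FPKM, a ratio of 0.145 with a 95% counting interval of 0.132 to 0.159. Mest, an imprinted gene, was at 86.7 and 13.9 FPKM (−2.56), and Spon2, a secreted matrix protein, at 12.2 and 1.38 FPKM (−2.47). Ifi27, named for its induction by interferon, was lower, at 85.6 and 14.8 FPKM (−2.46), whereas its relative Ifi27l2a was at 18.9 and 184 FPKM (3.22). The authors' deposited table gave q-values of 0.0358 for S100a4 and 0.352 for Mgp.

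Cell cycle genes were lower as a group. Of 39 measured, 16 were at least 2-fold lower and none higher, with a median of −0.85, below all random lists. Beside them, the median of mitochondrially encoded transcripts was −1.24, that of endothelial markers −0.57 and that of mesothelial markers −0.96. Mki67, a marker of cycling cells, was at 17.1 and 5.36 FPKM (log2 change −1.51), Ccnb2, a mitotic cyclin, at 5.32 and 0.747 FPKM (−1.86), Cenpa, the centromeric histone, at 8.46 and 1.99 FPKM (−1.66) and Ccna2, cyclin A, at 9.65 and 2.55 FPKM (−1.59). Of 22 p53 targets, 2 were lower, Gtse1 (−1.05) and Sesn1 (−1.03), Zmat3 lay within 2-fold at −0.87, and the median of 0.11 lay at percentile 70.5. Of 16 senescence genes, 2 were higher, the cytokine genes Il6 (4.82 and 26.6 FPKM, 2.25) and Il1a (62.0 and 214 FPKM, 1.77), and 2 were lower, Igfbp3 (−1.28) and Mmp3 (−1.24). The senescence median was −0.01 at percentile 28.8 and its mean 0.07.

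Of 22 cell death genes, 7 were higher and none lower by 2-fold, with a median of 0.62, above all random lists. The highest was Zbp1 (4.99), which is also on the type I interferon list, so this list is not independent of the interferon response. Tnfsf10, which encodes the death ligand TRAIL, was at 0.684 and 21.5 FPKM (log2 change 3.74), and Mlkl, the executioner of necroptosis, at 30.7 and 151 FPKM (2.26). Of 26 genes of the integrated stress and unfolded protein responses, 7 were higher, with a median of 0.46, above all random lists. Immediate early genes, which share Atf3 (1.25) with this list, had a median of 0.54. The highest were Ddit3, which encodes the transcription factor CHOP, at 29.4 and 163 FPKM (2.43), Trib3, a pseudokinase induced by it, at 9.40 and 47.4 FPKM (2.22) and Ppp1r15a, a phosphatase subunit that reverses eIF2 alpha phosphorylation, at 29.4 and 104 FPKM (1.79). Hspa5, the main chaperone of the endoplasmic reticulum, lay within 2-fold at 394 and 508 FPKM.

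Sterol synthesis genes were lower as a group, with 10 of 20 at least 2-fold lower and all 20 below 0, and the median of −1.05 lay below all random lists, beside medians of −0.57 for endothelial and −0.96 for mesothelial markers. Cyp51, a demethylase of lanosterol, was at 14.0 and 3.18 FPKM (log2 change −1.85), and Fdps, a prenyl diphosphate synthase, at 32.7 and 9.42 FPKM (−1.69). Of 13 estrogen-responsive genes, 2 were lower, Igfbp4 (−1.24) and Ltf (−1.16), Ccnd1 lay within 2-fold at −0.58, and the median of −0.42 lay at percentile 0.12. Mitochondrially encoded transcripts were lower, 10 of 13 by at least 2-fold and all 13 below 0, with a median of −1.24, below all random lists. All genes of the mitochondrial chromosome, not only these 13, made up 3.23% of summed FPKM with vehicle and 1.72% with 4-OHT. Levels among the 13 were uneven, with mt-Co1 at 4185 and 2519 FPKM and mt-Co2 at 19.9 and 7.85 FPKM, and the cause was not tested. The cytochrome b transcript mt-Cytb was at 920 and 194 FPKM (−2.24) and mt-Nd1 at 1207 and 433 FPKM (−1.48), while mt-Nd3, whose transcript is short, was at 3.01 and 0.185 FPKM (−1.76). Immediate early genes, which respond to handling among other stimuli, were higher in 5 of 15 cases, with a median of 0.54, above all random lists, namely Egr1 (1.48), Klf6 (1.46), Atf3 (1.25), Klf4 (1.13) and Zfp36 (1.01).

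Transcripts of macrophages and endothelium were abundant in both libraries. The median FPKM was 299 with vehicle and 256 with 4-OHT over macrophage markers and 125 and 65.7 over endothelial markers, beside 95.2 and 58.9 over contractile, 19.6 and 6.15 over matrix and 17.1 and 12.5 over quiescent stellate genes. Levels overlapped between these lists, with the macrophage gene Timd4 at 3.18 and 4.14 FPKM and the matrix gene Sparc at 620 and 450 FPKM. Lyz2, macrophage lysozyme, was at 3050 FPKM with vehicle and 1353 FPKM with 4-OHT, C1qa, a complement gene of tissue macrophages, at 515 and 430 FPKM, and Clec4f, a Kupffer cell lectin, at 144 and 202 FPKM. The endothelial genes Cdh5 (300 and 320 FPKM) and Egfl7 (421 and 675 FPKM) lay above Acta2 (86.8 and 8.87 FPKM), Col1a1 (24.1 and 7.66 FPKM) and Des (12.6 and 7.15 FPKM). Of 18 macrophage markers, 3 were lower, Vsig4 (log2 change −1.20), Itgam (−1.17) and Lyz2 (−1.17), and 15 lay within 2-fold. Their median of −0.21 lay at percentile 3.50, inside the range of random lists, or at percentile 1.65 with 10 bins. Of 16 endothelial markers, 2 were lower, the sinusoidal genes Clec4g (45.4 and 18.9 FPKM, −1.22) and Stab2 (147 and 68.5 FPKM, −1.09), and 1 was higher, Flt1 (3.59 and 8.37 FPKM, 1.03, or 0.99 after centring), with a median of −0.57, below all random lists.

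**Figure D3:**
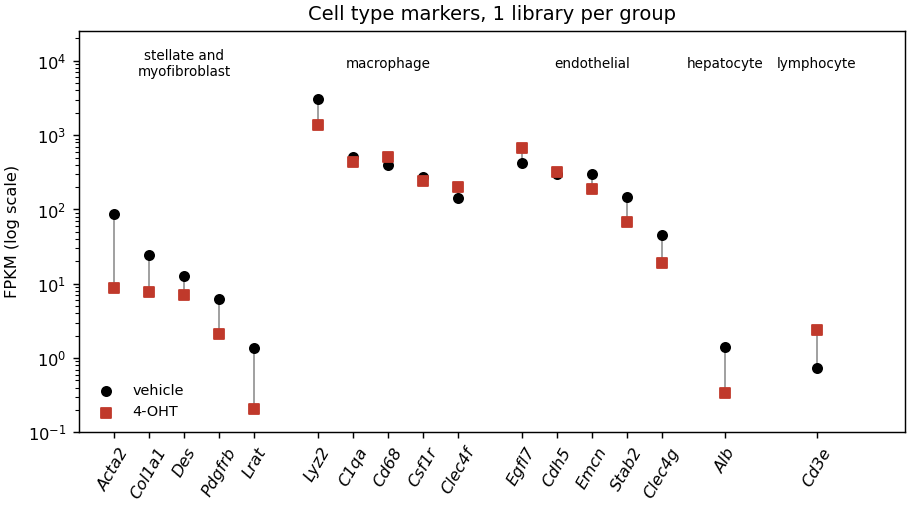
FPKM on a log axis of 17 marker genes in the vehicle library (black circles) and the 4-OHT library (red squares), grouped by cell type, with 1 library per group and no error bars. Lyz2 is at 3050 and 1353 FPKM, whereas Acta2 is at 86.8 and 8.87 FPKM.

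The remaining marker lists had few measured genes. Of 5 mesothelial markers, 2 were lower, Upk3b (1.78 and 0.146 FPKM, log2 change −1.28) and Lrrn4 (−1.05), Wt1 was at −0.96, and the median of −0.96 lay at percentile 0.21. The 3 smooth muscle markers, Rgs4 (−0.97), Cnn1 (−0.86) and Smtn (−0.15), had a median at percentile 1.55, or 3.82 with a pseudocount of 5. Of the 3 portal fibroblast markers, Fmo2 was lower (−1.11), Cd34 (−0.62) and Thy1 (0.12) lay within 2-fold, and the median was at percentile 3.94. Of 6 lymphocyte markers, none differed by 2-fold with 1 FPKM added, which shrinks the change of genes at such low levels. Without it, the ratio was 3.29 for Cd3e and 0.365 for Klrb1c. The list median of 0.64 lay at percentile 99.6, or 88.1 for the list mean of 0.31. Cd3e was at 0.725 and 2.39 FPKM and Trbc2 at 2.86 and 6.16 FPKM, a ratio of 2.15 (95% counting interval 1.53 to 3.03), while Klrb1c was at 2.54 and 0.927 FPKM. The 3 dendritic cell markers, Itgax (88.4 and 50.8 FPKM, −0.79), Clec9a (−0.05) and Zbtb46 (0.23), had a median at percentile 37.2. Lists with fewer than 3 measured genes gave values only. Of hepatocyte genes, Trf was at 58.5 and 19.6 FPKM and Alb at 1.41 and 0.334 FPKM; the cholangiocyte gene Krt19 was at 4.39 and 2.57 FPKM, and of neutrophil genes Csf3r was at 7.38 and 17.6 FPKM and S100a8 at 2.58 and 1.04 FPKM. No red cell gene of the list was measured.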

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

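Counts of protein-coding genes and of genes with longer transcripts were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because there was 1 library per group, and for the same reason no library could be left out. Centring and trimmed-mean scaling moved the median change by 0.04 and 0.02, giving 744 and 757 higher and 521 and 492 lower genes. The 783 higher genes became 456 with a pseudocount of 5, 1581 at 1.5-fold and 293 at 4-fold. The 472 lower genes became 859 with a pseudocount of 0.1, 163 with a pseudocount of 5, 1386 at 1.5-fold and 77 at 4-fold. These follow from the thresholds and, for pseudocounts, from the weight of low genes. Protein-coding genes alone gave 562 and 374, and genes with longest transcripts of at least 300 bases 665 and 391. In the authors' deposited table, 129 lower calls became 59 at a q-value under 0.01.

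Of 300 alternatives for 30 list medians, 284 were counted as kept, 9 gained and 7 lost the call, and no called list changed sign. A list that was not called was counted as kept also when its sign changed, as for senescence genes (median −0.01, mean 0.07). Interferons and receptors gained it at 0.33 (pseudocount 5), 0.47 (no minimum), 0.35 (unmatched) and 0.84 (mean). Macrophage markers gained it at −0.21 (10 bins, unmatched) and −0.22 (mean), and portal fibroblast markers at −0.35 (pseudocount 5) and −0.62 (unmatched). The call was lost for MHC class II at 0.69 (mean), TGF-beta, PDGF and YAP at −0.13 (minimum 5), quiescent stellate genes at −0.14 (no minimum) and −0.076 (minimum 5), lymphocyte markers at 0.31 (mean), and smooth muscle markers at −0.26 (pseudocount 5) and −0.66 (mean). The cause was not tested. A minimum of 5 left under 3 members, and so no value, in the lymphocyte, dendritic, mesothelial, portal fibroblast and smooth muscle lists. Of 484 alternatives for named genes, 447 kept their side of 2-fold, 13 passed it and 24 fell short. Depth limits genes near the floor of 3 fragments.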

Other observations

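The tests of a response within macrophages, of fewer stellate cells and of Ch25h were written before their values were seen; the other tests below were chosen after the result was seen, as were the genes of the next 2 paragraphs.

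Genes outside the fixed lists showed further differences between the libraries. Acod1, the enzyme that makes itaconate in activated macrophages, was at 10.96 FPKM with vehicle and 188 FPKM with 4-OHT (log2 change 3.98), Cd40, a costimulatory receptor, at 5.69 and 60.6 FPKM (3.20), and Nos2, inducible nitric oxide synthase, at 0.669 and 9.33 FPKM (2.63). The complement genes Cfb (7.89 and 157 FPKM, 4.15) and C3 (19.4 and 114 FPKM, 2.49) were higher. Fabp4, a fatty acid-binding protein, was at 164 and 48.2 FPKM (−1.75), and Apoe, an apolipoprotein abundant in macrophages, at 1455 and 595 FPKM (−1.29). The lipid synthesis genes Scd1 (14.6 and 4.06 FPKM, −1.63) and Fasn (35.8 and 14.7 FPKM, −1.23) were lower beside Scd2. Mmp12, a macrophage elastase, was at 3701 FPKM with vehicle, among the most abundant nuclear protein-coding genes, and at 2961 FPKM with 4-OHT.

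A large difference did not always carry a low q-value in the authors' deposited table. Of protein-coding genes with at least 5 FPKM that differed by at least 4-fold, 25 had a q-value of 0.05 or more in the authors' deposited table, 22 higher and 3 lower. H2-K1, a classical MHC class I gene, was at 562 and 3156 FPKM with a q-value of 0.353 in the authors' deposited table. Rnf213, a giant ubiquitin ligase, was at 61.0 and 536 FPKM with 0.548 in the authors' deposited table.

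Interferon-stimulated genes were higher in the 4-OHT library, in cultures whose RNA was rich in macrophage transcripts. A larger share of macrophages would raise macrophage markers, but their median change was −0.21 (95% bootstrap interval over 18 genes, −0.40 to 0.15). This argues against a larger share as the cause, unless the markers were also lower per cell. The interval covers the spread over marker genes, not the spread between cultures. Interferon-inducible genes picked for expression in blood-derived cells (10 given, 7 measured) were all at least 2-fold higher, with a median of 3.11 (interval 1.81 to 3.62), among them Fcgr1 at 7.38 and 71.2 FPKM and Ms4a6b at 9.96 and 134 FPKM. Slfn1, Slfn4 and Il27 reached the minimum of 1 FPKM only with 4-OHT. Whether each gene is restricted to such cells was not tested. Higher values of these genes would follow from a response within blood-derived cells of the culture, such as its macrophages, whether by loss of Adar there or by interferon from other cells. The genes do not tell macrophages from other blood-derived cells. The median of 6 lymphocyte markers was 0.64, and of neutrophil genes Csf3r was at 7.38 and 17.6 FPKM and S100a8 at 2.58 and 1.04 FPKM. How much of the response arose in stellate cells stays open. An effect of 4-OHT itself cannot be told apart from loss of Adar, since no library had 4-OHT without the floxed allele; estrogen-responsive genes had a median of −0.42.

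Matrix genes, and 5 of 22 contractile genes, were lower in the 4-OHT library. A return of an unchanged share of stellate cells to quiescence would raise quiescent genes, but their median was −0.33 (interval −0.74 to 0.26), −0.14 (−0.53 to 0.04) without a minimum value and −0.076 (−0.75 to 0.43) for genes of at least 5 FPKM. These intervals argue against a rise of the list by 0.5 or more, but with 7 of 20 members above 0 a return of some genes stays open. The list cannot decide on quiescence of the stellate cells themselves. Macrophage and endothelial transcripts were abundant, and not every member need come from stellate cells. Plin2 was at 191 and 356 FPKM, whereas Lrat was at 1.36 and 0.209 FPKM. Of 14 stellate and pericyte genes given outside the contractile and matrix lists, 8 were measured, with a median of −0.22 (interval −0.92 to 0.52), ranging from Itga8 (−1.45) to Kcnj8 (0.54). Lower expression per cell and fewer stellate cells, which may account for part of the pattern, therefore cannot be told apart with 8 genes at low levels that went both ways, and fewer mesothelial or smooth muscle cells stay open too, with marker medians of −0.96 over 5 genes and −0.86 over 3.

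Sterol synthesis genes were lower in the 4-OHT library. Ch25h, the interferon-induced enzyme that makes 25-hydroxycholesterol, a suppressor of sterol gene transcription, was at 23.1 and 89.5 FPKM (log2 change 1.91). Since interferon-stimulated genes were higher as a set, a higher Ch25h was to be expected whether or not it acted on sterol genes, so this value does not test 25-hydroxycholesterol as the cause, which stays open, as does an effect of 4-OHT itself.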
